A study of Oryza sativa Japonica Group with 6 samples.

How the data were processed

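RNA from the shoots of 6 rice samples, 3 control and 3 nitrogen-deficient, was measured on single-colour Agilent arrays with 45151 spots each. The deposited scanner files hold spot intensities made with Agilent Feature Extraction 10.5.1.1, and per the file headers the processed intensity is background-subtracted and detrended within an array but not scaled between arrays. The same deposited files hold other columns, per-spot flags for signal well above background, saturation and outliers. The authors also deposited log2 values, and each column equalled the log2 processed intensity minus the array's 75th percentile over all spots. How that scaling was chosen is not given in the sources used here. The group of each array came from its label, and its slide and scan day came from the scanner files.

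Log2 processed intensities were averaged over the spots of a probe, spots marked as outliers were left out, and the 75th percentile over gene probes of the array was subtracted. Of 42418 probes, 31954 were well above background on every array of at least 1 group and were tested, and 10464 were not. The test was lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with no covariate, and Benjamini-Hochberg adjustment over the tested probes at a threshold of 0.05. For loci, the probe with the highest mean over the arrays stood for the locus. A difference is called a bound ("at least") where no array of a group was well above background. For a bound, signals of that group were raised to the lowest signal well above background on the array. Where this changed nothing, the bound equals the estimate. Files were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The number of arrays limits the precision.

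In all, 31 gene lists were fixed before the data were examined, from locus identifiers and from words in the locus descriptions. Symbols come from these lists, since the array gives only descriptions. Members whose description plainly named another protein were left out before any difference was computed, 463 in all, of which 361 matched the cell division words through descriptions of F-box or tetracycline-related proteins. Lists were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation and with fry. The p of fry asks whether the genes of a list move on balance one way, and its mixed p asks whether they move in either direction. The main lists were nitrate transport, ammonium transport, nitrogen assimilation, reductant supply, nitrate regulators, type-A response regulators, light reactions, cytosolic ribosomal proteins and phosphate starvation. The others were hemoglobin, cytokinin metabolism, Calvin cycle, plastid ribosomal proteins, autophagy, amino acid biosynthesis, amino acid transport, sulfur assimilation, iron homeostasis, starch and sucrose, phenylpropanoids, circadian clock, heat shock, abscisic acid and dehydration, jasmonate and wounding, defence, redox enzymes, auxin, cell wall, cell division, root markers and seed storage.

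The rule for named genes, fixed before the data were examined, took the 10 largest rises and 10 largest falls among called loci with groups apart and a described product, up to 4 members of each main list, and up to 3 of each other list called by camera. After the first table of named genes was seen, descriptions reading "no hit" or "non-protein coding" were also taken as naming no product. This dropped the locus Os08g0466600 (-2.70) and brought IRO2 into the 10 largest falls. Loci behind counts of 5 or fewer were named after their values were seen.

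The fit was tested on simulated data made from the arrays, with 200 of 31936 probes changed. Changes of 0.5, 1 and 2 on the log2 scale were recovered in 21%, 92% and 96% of cases, with 9 false calls. With so few changed probes the adjusted threshold is stricter than in the real comparison, so these shares do not carry over to it. Of 200 simulated lists of 30 genes, all 20 shifted by 0.3 were called and 0 of the unshifted ones. The simulated genes varied independently of each other, so this result does not carry over to lists whose genes vary together. The estimated correlation was 0.86 in the cytosolic ribosomal protein list.

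Alternatives planned before the data were examined were quantile, median and detected-probe 75th percentile scaling, normexp background correction with an offset of 50 followed by quantile or 75th percentile scaling, the authors' values, no filter, a filter on all 6 arrays, a trended robust variance, array weights, slide as a fixed or random block, the slide of both groups alone, scan day and replicate number as blocks, leaving out each array, other thresholds, and the mean of a locus's probes. Each other slide held a single array, so slide as a fixed block is nearly the same fit as the slide of both groups alone. Scan day as a block is nearly the fit without control replicate 3, the only array of its scan day. Scaling to 7 spike-in probes was chosen after seeing the data. In that scaling the prior degrees of freedom of limma rose from 2.61 to 71.9, because the spread of the spike-ins enters every probe alike, so its calls are not independent of each other.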

Results

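Shoots of rice seedlings (cultivar Nipponbare, 7 days old, grown in a nutrient solution) were sampled at 6 h, 3 times from a solution without ammonium nitrate and 3 times from the control solution. RNA of each sample was labelled with 1 dye and hybridised to 1 Agilent array, so there were 6 arrays and 3 per group. Between 74.1% and 77.6% of the probes lay well above background on each array, and the 75th percentile of the processed signal ranged from 2314 to 3671. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, and the number of arrays limits the precision. Of 3 slides, 1 held control replicates 1 and 2 with nitrogen-deficient replicates 2 and 3. Control replicate 3 was alone on another slide and scan day, and nitrogen-deficient replicate 1 was alone on the third slide.

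The comparison asked which shoot genes differed in RNA level after 6 h without nitrogen. Relative to the 75th percentile of each array, genes of the cytosolic ribosome were lower as a group, with 102 of 147 measured loci past the threshold and 0 higher (camera of limma, adjusted p = 1.5e-28, but adjusted p = 0.56 with an estimated correlation). Type-A response regulators, which the hormone cytokinin induces, were lower in 6 of 7 loci, by a mean of -0.79 on the log2 scale (adjusted p = 0.56 with an estimated correlation in limma). Of 11 regulators of the nitrate response, 6 were lower, among them the repressor genes HHO3, HHO2, LBD37 and LBD39 (adjusted p = 0.56 with an estimated correlation in limma). The gene with the largest rise among those with a described product was Os03g0254200, an amino acid transporter family member, 13.8-fold higher. Among the same loci the largest fall was in Os01g0368900, a glutaredoxin, 15.1-fold lower.

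Of 31954 probes tested with limma, 3338 were higher and 4376 lower under nitrogen deficiency at an adjusted p under 0.05, and 12495 passed an unadjusted p of 0.05. At least 2-fold differences were seen in 118 of the higher and 262 of the lower probes. By locus, 2252 were higher and 2805 lower of 21715, and 94.7% of these changed by less than 2-fold. The groups did not overlap in 44.5% of the loci tested, where chance gives 10%. With slide as a block the counts were 1593 higher and 3025 lower, and within the slide that held both groups they were 1592 and 3022. Both rest on the same arrays, control replicates 1 and 2 and nitrogen-deficient replicates 2 and 3, so they are not separate checks. Without 1 array the higher probes numbered 2153, 1483 and 4348 (control replicates 1, 2 and 3), 956, 941 and 1321 (nitrogen-deficient replicates 1, 2 and 3). The lower probes numbered 3374, 2483 and 5213 without the control replicates and 2055, 1755 and 2532 without the nitrogen-deficient replicates, in the same order.

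All directions are relative to the bulk of the probes on an array. Scaling to RNA spiked in before labelling, chosen after seeing the data, moved the median of all loci from 0.03 to 0.39 on the log2 scale, a shift of 0.36. The labels do not state whether equal amounts of total RNA and spike-in entered each labelling, so values in that scaling are not a measure of RNA level on their own. The share of called probes that were higher was then 95.7%, against 43.3% in the main scaling. Lists whose mean changed sign under that scaling are named as such. The scaling shifts every locus alike, so a negative mean smaller in size than the shift changes sign by construction. Such a list did not rise relative to other genes: light reactions, at 0.08, stayed below the median of 0.39. Camera still passed the called lists whose mean changed sign, with adjusted p up to 0.026 (Calvin cycle).

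Os03g0254200 went from a mean log2 signal of -3.06 ± 0.56 (SD, n = 3) in control shoots to 0.73 ± 0.06 (SD, n = 3), a difference of 3.79 (SE 0.26, adjusted p = 0.0015 by limma). Os06g0228500, of the same transporter family, rose by 2.11 (SE 0.17), and the amino acid carrier Os01g0882800 rose by 1.82 (SE 0.24). The nodulin-like proteins Os05g0409500 (MtN21) and Os04g0538400 rose by 2.85 (SE 0.31) and 2.11 (SE 0.15). Allantoinase (Os04g0680400), an enzyme of ureide breakdown, rose by 2.54 (SE 0.14, adjusted p = 0.0011), and proline dehydrogenase (Os10g0550900), which starts proline breakdown, by 1.94 (SE 0.11). A cytochrome P450 (Os02g0221900) rose by 2.24 (SE 0.14). The U-box protein Os04g0584500 was not well above background on any control array, so its rise is a bound, at least 5.44-fold. The Myb protein Os07g0443500 rose by 2.37 (SE 0.53), but its adjusted p was 0.076 with slide as a block and reached 0.078 without control replicate 2 or any 1 of the nitrogen-deficient arrays.

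Among the largest falls were the glutaredoxins Os01g0368900, from 1.93 ± 0.35 to -1.99 ± 0.32 (SD, n = 3 each), and Os11g0655900, with a difference of -3.17 (SE 0.15). The ammonium transporter AMT2;3 (Os01g0831300) was at least 7.87-fold lower, a bound because no nitrogen-deficient array was well above background. The protein kinase Os11g0113700 fell by 2.63 (SE 0.21) and allantoin permease (Os12g0503000) fell by 2.41 (SE 0.34). The Nramp6-like metal transporter Os07g0258400 fell by 2.34 (SE 0.21), Os12g0538700 (AT.I.24-1 protein) was 4.92-fold lower, and IRO2 (Os01g0952800), a bHLH regulator of the iron deficiency response, fell by 2.22 (SE 0.24). The embryonic abundant protein Os05g0349800 was at least 5.28-fold lower, with an adjusted p of 0.093 with slide as a block and up to 0.079 without control replicate 2 or any 1 nitrogen-deficient array. The membrane protein PM 19 (Os05g0381400) fell by 2.45 (SE 0.60), with an adjusted p of 0.11 with slide as a block and up to 0.083 without control replicate 1 or 3 or nitrogen-deficient replicate 1 or 3.

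Of 31 gene lists fixed before the data were examined, camera called 9 lower and 2 higher with its preset correlation of 0.01. None of these calls held with an estimated correlation. That setting called 0 of the 31 lists. Defence, with an estimated correlation near the preset one (0.02), also went to an adjusted p of 0.56 by camera. The setting rests on the spread of only 3 arrays per group, so a call lost there does not show that correlation undid that list. By fry, which asks only whether a list moves on balance one way, light reactions, Calvin cycle and cell division did not pass. The other lists called by camera passed by fry, with adjusted p from 0.0035 to 0.037. The mean log2 differences of the main lists on each array are plotted.

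**Figure D1:**
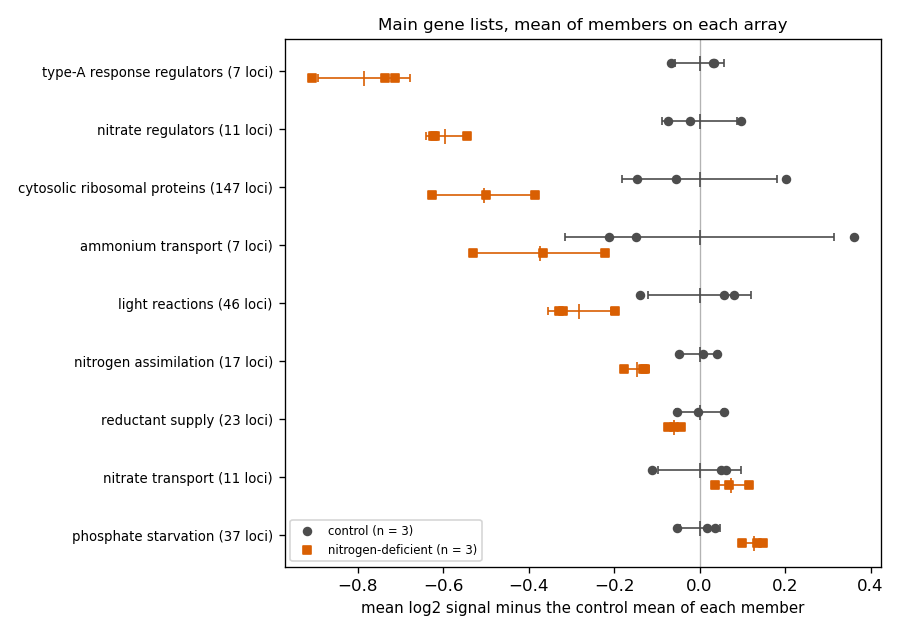
Mean log2 signal of the 9 main gene lists on each array, minus the control mean of each member, with 3 control and 3 nitrogen-deficient arrays; bars are the mean and SD over arrays. Cytosolic ribosomal protein loci lie at -0.63, -0.50 and -0.39 on the nitrogen-deficient arrays. The light reaction list, at a mean of -0.28, changes sign to 0.08 with spike-in scaling, which shifts every locus alike.

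Cytosolic ribosomal proteins, the protein part of the translation machinery outside organelles, had a mean difference of -0.50 (SD over loci 0.18). Of 147 measured loci 0 rose, 102 fell and 45 did not pass, and 134 fell when adjusted over the list alone. Camera gave an adjusted p of 1.5e-28 (limma), and the adjusted p = 0.56 with an estimated correlation. The mean was -0.52 both with slide as a block and within the slide, and -0.14 with spike-in scaling. Os12g0406200 (S3a) fell by 0.84 (SE 0.10), Os02g0534800 (S14) fell by 0.77 (SE 0.11), Os02g0229000 (S19-like) fell by 0.72 (SE 0.10) and Os08g0558800 (L10a) fell by 0.60 (SE 0.07). Under spike-in scaling the last 3 kept their sign but lost the call.

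Plastid ribosomal proteins had a mean of -0.32, which changed sign to 0.04 with spike-in scaling. Of 47 loci 27 fell, 0 rose and 20 did not pass, and 31 fell when adjusted over the list alone. The camera adjusted p was 4.7e-11, and the adjusted p = 0.56 with an estimated correlation. The mean was -0.33 with slide as a block and within the slide. Os09g0279500 fell by 0.68 (SE 0.09), Os02g0259600 (L21) fell by 0.58 (SE 0.08) and Os03g0856500 fell by 0.56 (SE 0.09), and all 3 lost the call with spike-in scaling.

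Type-A response regulators, which act as feedback inhibitors of cytokinin signalling, fell in 6 of 7 measured loci, also when adjusted over the list alone. Camera gave an adjusted p of 2.7e-05, and the adjusted p = 0.56 with an estimated correlation. The list mean was -0.76 with slide as a block and within the slide, and -0.42 with spike-in scaling. RR10 (Os12g0139400) fell by 1.05 (SE 0.12), RR6 (Os04g0673300) fell by 1.02 (SE 0.13), RR2 (Os02g0557800) fell by 0.84 (SE 0.09) and RR4 (Os01g0952500) fell by 0.72 (SE 0.06). The RR4 call was lost with spike-in scaling.

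Regulators of the nitrate response had a mean of -0.60 and a median of -0.24 over 11 loci, of which 1 rose, 6 fell and 4 did not pass, with the same counts when adjusted over the list alone. With camera the adjusted p was 0.013, and the adjusted p = 0.56 with an estimated correlation. The mean was -0.66 with slide as a block and within the slide, and -0.23 with spike-in scaling. Restricting the probes to those well above background on all 6 arrays gave -0.45 and ended the call, with an adjusted p of 0.0507. HHO3 (Os03g0764600) fell by 1.88 (SE 0.09), LBD39 (Os07g0589000) fell by 1.47 (SE 0.12) and HHO2 (Os07g0119300) fell by 1.15 (SE 0.08). LBD37 (Os03g0445700) was at least 4.14-fold lower, a bound because no nitrogen-deficient array was well above background. Raising its signals to the floor of a bound changed nothing, so the bound equals the estimate. Its log2 difference was -2.05, and -1.69 with spike-in scaling. The riser, named after its value was seen, was NLP1 (Os03g0131100), a NIN-like activator, with 0.64 (SE 0.11) and an adjusted p of 0.066 with slide as a block.

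Nitrogen assimilation genes went both ways: of 17 loci 4 rose, 6 fell and 7 did not pass, and 5 rose and 6 fell when adjusted over the list alone. The mean was -0.15 (-0.13 with slide as a block and within the slide), and it changed sign to 0.22 with spike-in scaling. The list was not called by camera (adjusted p = 0.65). NADH-GOGAT2 (Os05g0555600), a glutamate synthase, fell by 1.23 (SE 0.10). The glutamine synthetases GS1;2 (Os03g0223400, cytosolic) and GS2 (Os04g0659100, plastid) fell, with differences of -0.88 (SE 0.07) and -0.44 (SE 0.06). The GS2 call was lost with spike-in scaling. NIA1 (Os08g0468100), a nitrate reductase, rose by 0.56 (SE 0.07). The other risers, named after their values were seen, were NADH-GOGAT1 (Os01g0681900, 0.47), NIA2 (Os08g0468700, 0.32) and AS2 (Os06g0265000, 0.22). NIA2 and AS2 lost the call with slide as a block (adjusted p = 0.065 and 0.11), and NADH-GOGAT1 lost it without nitrogen-deficient replicate 2 (adjusted p = 0.052). With the mean of its probes, the gene Os01g0681900 (NADH-GOGAT1) had a difference of 0.09 and an adjusted p of 0.48. AS1 (Os03g0291500), an asparagine synthetase also chosen after its value was seen, fell by 1.97 (SE 0.32).

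Ammonium transporters also went both ways, with 3 loci higher, 2 lower and 2 not past the threshold of 7 measured, and the same counts when adjusted over the list alone. The mean was -0.37 (-0.27 with slide as a block and within the slide), with a camera adjusted p of 0.93. It ranged from -0.48 without control replicate 2 to -0.19 without control replicate 3, was -0.01 with spike-in scaling, and turned positive with the filter on all 6 arrays, which removes AMT2;3. AMT1;1 (Os04g0509600) rose by 1.07 (SE 0.15). AMT3;1 (Os01g0870300) rose by 0.38 (SE 0.07), but its adjusted p reached 0.064 without any 1 of the nitrogen-deficient arrays. AMT1;3 (Os02g0620600), named after its value was seen, rose by 0.44 (SE 0.10), with an adjusted p of up to 0.083 without control replicate 1 or 2 or nitrogen-deficient replicate 1 or 2, and of up to 0.098 over all alternatives. AMT2;1 (Os05g0468700) fell by 0.56 (SE 0.07), a call lost with spike-in scaling, and AMT2;3 is given above.

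**Figure D2:**
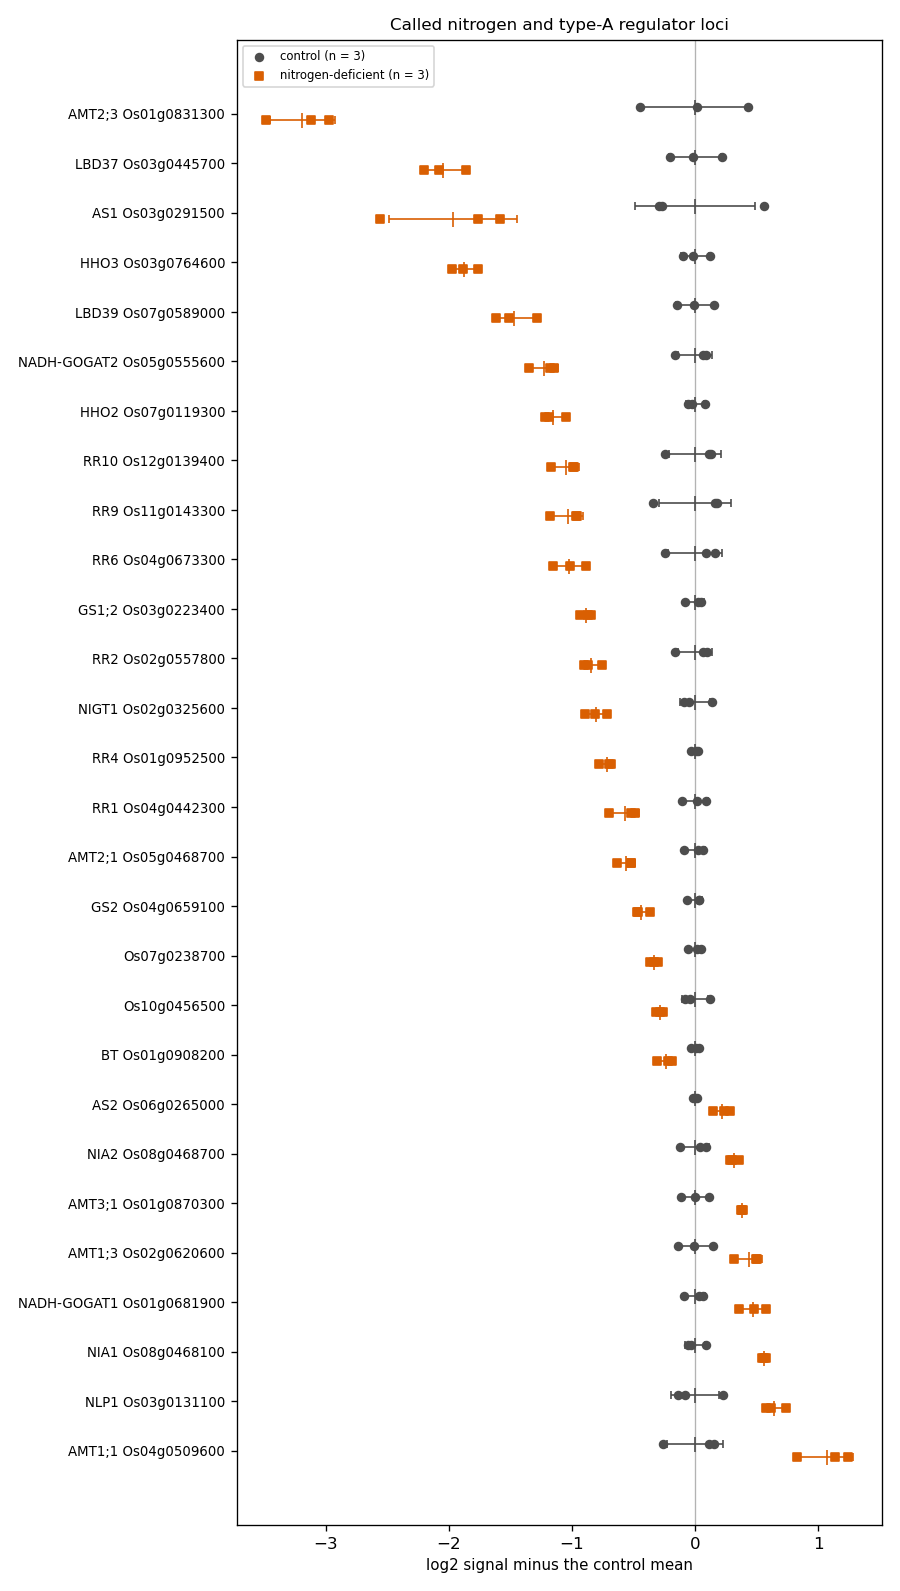
Log2 signal of the called loci of the ammonium transport, nitrogen assimilation, nitrate regulator and type-A regulator lists on each of 6 arrays, minus the control mean, with bars for the mean and SD over 3 arrays. HHO3 shows a difference of -1.88 and AMT1;1 one of 1.07, while no nitrogen-deficient point of AMT2;3 or LBD37 was well above background. The fall of AMT2;3 is a bound of at least 7.87-fold, and that of LBD37 is a bound of at least 4.14-fold, which equals its estimate.

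Nitrate transporters gave 1 locus higher, 0 lower and 10 not past the threshold of 11 measured, and 1 higher when adjusted over the list alone. The mean was 0.07 (0.08 with slide as a block, 0.07 within the slide), and the camera adjusted p was 0.54. Without control replicate 2 the mean was 0.02, and without nitrogen-deficient replicate 1 it was 0.05. The nitrate transporter Os10g0110800 rose by 0.45 (SE 0.07), while NPF8.9 (Os03g0235900) had a difference of 0.30 (SE 0.09, adjusted p = 0.059).

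Genes that supply reductant for nitrate assimilation had a mean of -0.06 (-0.08 with slide as a block, -0.09 within the slide), which changed sign to 0.30 with spike-in scaling and was -0.03 without control replicate 2. Of 23 loci 3 rose, 5 fell and 15 did not pass, the same when adjusted over the list alone, and the camera adjusted p was 0.65. The ferredoxins Os03g0685000, Os07g0489800 and Os08g0104600 fell, with differences of -0.62, -0.63 and -0.37 (SE 0.07, 0.11 and 0.07), and all 3 calls were lost with spike-in scaling. Without nitrogen-deficient replicate 2 the adjusted p was 0.054 for Os07g0489800, and it reached 0.066 for Os08g0104600 without nitrogen-deficient replicate 2 or 3. With quantile normalization the gene Os08g0104600 had a difference of -0.17 (adjusted p = 0.090), and after normexp -0.09 (adjusted p = 0.29). The 6-phosphogluconate dehydrogenase Os11g0484500 rose by 0.41 (SE 0.07), with an adjusted p of 0.058 with slide as a block. The other called members, named after their values were seen, were root-type ferredoxin Os05g0443500 (0.37), root-type ferredoxin reductase Os03g0784700 (0.23), ferredoxin Os03g0659200 (-0.42) and leaf-type ferredoxin reductase Os06g0107700 (-0.37). Each of these 4 lost its call in at least 3 alternatives.

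Phosphate starvation genes had a mean of 0.13 (0.14 with slide as a block and within the slide), with 9 loci higher, 3 lower and 25 not past the threshold of 37, the same when adjusted over the list alone. The camera adjusted p was 0.18, and 0.047 with normexp correction before 75th percentile scaling, but 0.56 with an estimated correlation. The SPX-domain genes SPX2 (Os02g0202200), Os04g0573000 and Os02g0678200 rose by 1.15 (SE 0.08), 0.92 (SE 0.13) and 0.64 (SE 0.06). The array describes them only by that domain, so their roles may differ. The phosphodiesterase Os02g0514500 fell by 0.98 (SE 0.07). The other falls, named after their values were seen, were in the mitochondrial phosphate transporter Os03g0263400 (-0.49) and the phosphate transporter family member Os02g0593500 (-0.45). Both lost the call with spike-in scaling. Os02g0593500 had an adjusted p of 0.051 with slide as a block.

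Light reaction genes of photosynthesis had a mean of -0.28, which changed sign to 0.08 with spike-in scaling. Of 46 loci 0 rose, 14 fell and 32 did not pass, the same when adjusted over the list alone. Camera gave an adjusted p of 4.9e-07, and the adjusted p = 0.56 with an estimated correlation. The mean was -0.39 with slide as a block and -0.40 within the slide, and -0.13 with quantile normalization. By fry the adjusted p was 0.072. Os08g0252100 (photosystem II 47 kDa protein) fell by 0.95 (SE 0.08), Os06g0598100 (P680 apoprotein) fell by 0.92 (SE 0.12) and Os01g0881600 (reaction center J protein) fell by 0.64 (SE 0.07). These are normally plastid-encoded proteins, and the files do not show whether the probes read the nuclear loci or plastid transcripts. PsbW (Os01g0938100), a nuclear-encoded subunit, fell by 0.48 (SE 0.06), and it and Os01g0881600 lost the call with spike-in scaling.

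Calvin cycle genes had a mean of -0.20, which changed sign to 0.16 with spike-in scaling and was -0.30 with slide as a block and within the slide. Of 18 loci 1 rose, 6 fell and 11 did not pass, against 2 and 7 when adjusted over the list alone. With camera the adjusted p was 0.017, and the adjusted p = 0.65 with an estimated correlation. The call also ended with quantile normalization (mean -0.08), with normexp and quantile normalization, by fry (adjusted p = 0.083) and without control replicate 1 or 2 (adjusted p up to 0.068). The Rubisco small chain locus Os11g0298400 fell by 0.69 (SE 0.09). Among Rubisco large chain loci, whose probes have the same uncertainty about plastid transcripts, Os01g0791600 fell by 0.71 (SE 0.10) and Os02g0623400 rose by 0.50 (SE 0.07). All these Rubisco loci were dim, with control means of -3.45 (Os11g0298400), -5.08 (Os01g0791600) and -2.91 (Os02g0623400) on the log2 scale relative to the 75th percentile. Their changes need not hold for brighter Rubisco transcripts. The Os11g0298400 and Os01g0791600 calls were lost with spike-in scaling, and Os01g0791600 also lost it with normexp correction and 75th percentile scaling.

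Amino acid biosynthesis genes had a mean of -0.21 (-0.18 with slide as a block, -0.19 within the slide), which changed sign to 0.15 with spike-in scaling. Of 75 loci 3 rose, 25 fell and 47 did not pass, against 4 and 28 when adjusted over the list alone. The camera adjusted p was 7.25e-05, and the adjusted p = 0.56 with an estimated correlation. Falls were seen in enzymes of the aspartate family pathway: aspartate kinase Os03g0850400 (-1.92, SE 0.13), aspartokinase/homoserine dehydrogenase Os09g0294000 (-1.69, SE 0.11) and threonine synthase Os01g0693800 (-1.28, SE 0.10). The list keyword also took in isochorismate synthase (Os09g0361500, -0.64), an enzyme of salicylic acid synthesis rather than of an amino acid, whose call was lost with spike-in scaling. The 3 risers, named after their values were seen, were cysteine synthases: Os06g0149900 (0.47), Os02g0222100 (0.39) and Os03g0747800 (0.24), the last with an adjusted p of 0.078 with slide as a block.

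Sulfur assimilation genes had a mean of -0.34 (-0.38 with slide as a block and within the slide), which changed sign to 0.02 with spike-in scaling. Of 17 loci 1 rose, 7 fell and 9 did not pass, against 2 and 10 when adjusted over the list alone. Camera gave an adjusted p of 0.0054, and the adjusted p = 0.56 with an estimated correlation. Serine acetyltransferases Os03g0196600 and Os01g0720700, which make the carbon acceptor for cysteine, fell, with differences of -1.23 (SE 0.14) and -0.71 (SE 0.06), and sulfite reductase Os05g0503300 fell by 0.60 (SE 0.06). The last 2 lost the call with spike-in scaling. The riser, named after its value was seen, was sulfate transporter Os01g0719300 (0.47, SE 0.07).

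Autophagy genes, which serve the recycling of cell contents, had a mean of 0.20 (0.19 with slide as a block and within the slide), with 7 of 10 loci higher, 0 lower and 3 not past the threshold, the same when adjusted over the list alone. With camera the adjusted p was 0.017, and the adjusted p = 0.56 with an estimated correlation. The call also ended without control replicate 2 (adjusted p = 0.0503) and with spike-in scaling (adjusted p = 0.064). ATG8 (Os04g0624000) rose by 0.50 (SE 0.07). Autophagy 4a (Os04g0682000) rose by 0.37 (SE 0.08) and Apg9 (Os03g0248000) by 0.27 (SE 0.07), with adjusted p of 0.088 and 0.058 with slide as a block. Without single arrays their adjusted p reached 0.083 and 0.11, control replicate 2 and each nitrogen-deficient array ending both calls and control replicate 1 that of Apg9.

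Cell division genes had a mean of 0.10 (0.09 with slide as a block and within the slide), with 8 loci higher, 7 lower and 125 not past the threshold of 140, and 1 higher and 4 lower when adjusted over the list alone. The camera adjusted p was 0.014, and the adjusted p = 0.80 with an estimated correlation. The call also ended without control replicate 3 or nitrogen-deficient replicate 3 (adjusted p up to 0.15), with slide as a random block (adjusted p = 0.085), with scan day as a block and by fry (adjusted p = 0.26). Without nitrogen-deficient replicate 3 the mean was 0.06. The members with the smallest p were the cell division kinase Os05g0480000 (-0.78, SE 0.06) and the cyclins Os03g0617500 (-0.57, SE 0.07) and Os04g0552300 (0.44, SE 0.06). Both falls lost the call with spike-in scaling.

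Defence genes had a mean of -0.23 (-0.16 with slide as a block and within the slide), which changed sign to 0.13 with spike-in scaling. Of 87 loci 2 rose, 10 fell and 75 did not pass, against 2 and 9 when adjusted over the list alone. Camera gave an adjusted p of 0.017, and the adjusted p = 0.56 with an estimated correlation. The call also ended with slide as a random block (adjusted p = 0.085). The Bowman-Birk inhibitor Os03g0823400, a protease inhibitor, fell by 2.17 (SE 0.12) and chitinase Os02g0605900 fell by 0.74 (SE 0.10), the latter losing the call with spike-in scaling. PR-1a (Os02g0786900) rose by 0.56 (SE 0.07). The other riser, chitinase Os01g0860400 (0.85, SE 0.17), was named after its value was seen and had an adjusted p of 0.083 with slide as a block.

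Iron homeostasis genes went both ways, with 3 loci higher, 7 lower and 3 not past the threshold of 13, and 3 higher and 8 lower when adjusted over the list alone. The mean was -0.82 (-0.86 with slide as a block and within the slide, -0.46 with spike-in scaling), and camera did not call the list (adjusted p = 0.077). Without control replicate 1 or nitrogen-deficient replicate 1 the list passed (lowest adjusted p of these 0.034), as it did with normexp and quantile normalization and with spike-in scaling. Camera with an estimated correlation gave an adjusted p of 0.65. All members but IRO2 were named after their values were seen. The falls were in the iron transporters Os03g0667300 (-2.10, SE 0.17) and YSL2 (Os02g0649900, at least 3.22-fold lower), in NAS1 (Os03g0307300, -1.92, SE 0.52) and Os07g0689600 (-0.91), both nicotianamine synthases, and in the aminotransferases Os02g0306400 (-1.53) and Os11g0644800 (-0.73). The ferritins Os11g0106700 and Os12g0106000, which store iron, rose by 1.24 (SE 0.13) and 1.16 (SE 0.12), and the yellow stripe-like transporter Os04g0390500 rose by 0.63 (SE 0.07). With slide as a block the adjusted p was 0.16 for NAS1, 0.057 for Os07g0689600 and 0.064 for Os11g0644800. NAS1 also lost the call without control replicate 2 or 3 or any 1 nitrogen-deficient array, with an adjusted p of up to 0.12.

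**Figure D3:**
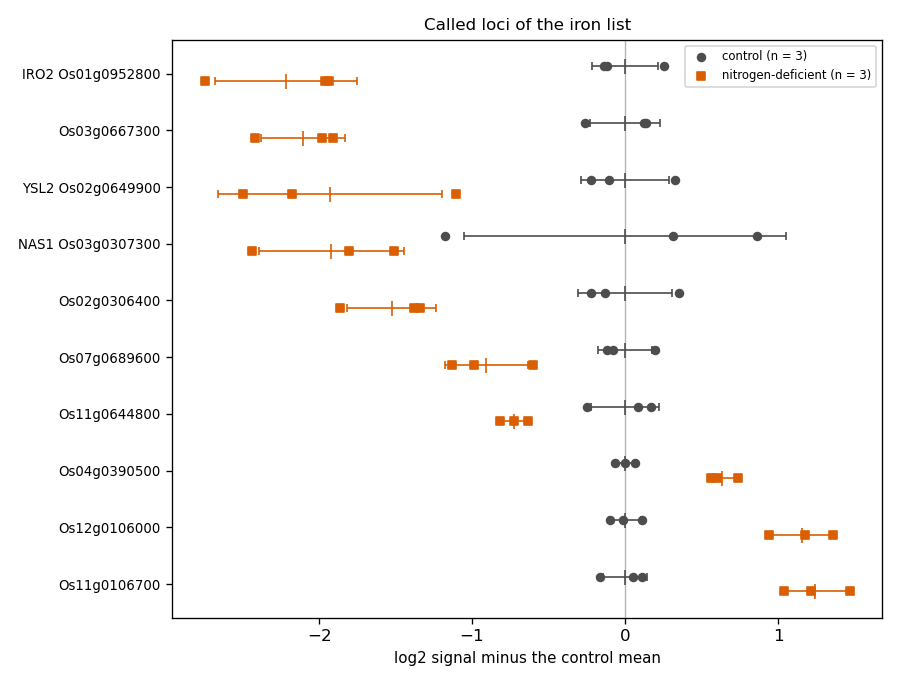
Log2 signal of the called loci of the iron list on each of 6 arrays, minus the control mean, with bars for the mean and SD over 3 arrays. Ferritin Os11g0106700 lies at a difference of 1.24 and IRO2 at -2.22, and the nitrogen-deficient points of YSL2 lie at background, so its fall is a bound of at least 3.22-fold.

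Of the 128 named loci past the threshold, 97 also passed with slide as a block, and 91 passed whichever 1 array was left out. Many of these loci were named for large changes or small p in the same arrays, which favours their passing. Of all 7714 called probes, 3769 were also called with slide as a block and 2636 without nitrogen-deficient replicate 2.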

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

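The test of the spike-in probes was chosen after the result was seen.

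RNA spiked in before labelling, which the main scaling does not use, gave a difference between the groups. The mean log2 signal of 7 spike-in probes over the 75th percentile of the array was 0.381, 0.479 and 0.697 in control replicates 1, 2 and 3, and 0.357, 0.081 and 0.036 in the nitrogen-deficient replicates in the same order. Relative to the spike-ins, the 75th percentile of the gene probes was thus higher under nitrogen deficiency by 0.36 on the log2 scale (1.28-fold, SD 0.16 and 0.17, exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). The labels do not state whether equal amounts of total RNA and spike-in entered each labelling, so this value and those scaled to the spike-ins are not a measure of RNA level on their own. No explanation of this difference was tested.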

How the results depend on the processing

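Scaling to the spike-ins was chosen after the data were seen, and the other alternatives were planned. The cause was not tested for any change below unless it is given.

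Probe counts stayed within 1.5 times of 3338 higher and 4376 lower under other scalings, backgrounds, variance models and filters, except these. No filter on dim probes gave 1572 and 2629, with more probes tested. Slide as a block gave 1593 higher, and the slide of both groups alone, nearly the same fit, gave 1592, with fewer arrays compared. Leaving out 1 array gave 941 to 4348 higher and 1755 to 5213 lower, in both cases lowest without nitrogen-deficient replicate 2 and highest without control replicate 3. By construction, an adjusted p under 0.01 gave 614 and 1317, one under 0.1 gave 5283 higher, and the 2-fold limit gave 118 and 262. Spike-in scaling gave 12261 higher and 556 lower, by construction a shift of every probe of an array.

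With the replicate number as a block, 1393 probes were higher and 2702 lower. Deviations from the group means correlated at 0.06, -0.16 and -0.15 between arrays of the same number. These values gave no sign that the numbers pair the samples. They cannot exclude a pairing, because some arrays of the same number were on different slides.

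With an estimated correlation camera no longer called the type-A response regulators (-0.79), nitrate regulators (-0.60), light reactions (-0.28) or cytosolic ribosomal proteins (-0.50), at an adjusted p of 0.56 each. That setting called 0 of the 31 lists, so it does not tell them apart. By fry, nitrogen assimilation (-0.15, adjusted p = 0.00096) and phosphate starvation (0.13, adjusted p = 0.022) passed and light reactions (-0.28, adjusted p = 0.072) did not. Phosphate starvation passed with normexp and 75th percentile scaling (0.12), and the nitrate regulators (-0.45) did not with the filter on all 6 arrays, which removes LBD37.

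Spike-in scaling changed the sign of the mean of abscisic acid and dehydration (0.14), amino acid biosynthesis (0.15), defence (0.13), Calvin cycle (0.16), light reactions (0.079), plastid ribosomal proteins (0.043), sulfur assimilation (0.020), nitrogen assimilation (0.22), reductant supply (0.30), cytokinin metabolism (0.15), heat shock (0.32), redox enzymes (0.32), starch and sucrose (0.33) and hemoglobin (0.34). It also reversed the genes Os03g0644400 (0.12), Os06g0125500 (0.13), Os06g0729800 (0.017), Os01g0665200 (0.14) and Os08g0428400 (0.16). These changes of sign follow by construction from the same shift of every locus. Of the named loci, 28 lost the call without the filter on dim probes and 31 with slide as a block. Dim signal limits the results: 10464 probes were not tested, and 61 loci were detected in 1 group only.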

Other observations

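Chosen after the result was seen were the tests of slide or scan day on the ribosomal protein genes, of the splits, and both tests on the iron genes; the bounds that decided the signal-matched test and the same-sign share were also changed after their values were seen.

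Amino acid transport genes had 13 of 42 loci higher, 3 lower and 26 not past the threshold (17 and 5 when adjusted over the list alone), with a mean of 0.18 (0.20 with slide as a block and within the slide) and a camera adjusted p of 0.077. The list passed with slide as a random block (adjusted p = 0.012), by fry (0.021), with spike-in scaling (0.017), with either normexp correction, with the mean of the probes of a locus, and without nitrogen-deficient replicate 1 or 3 (lowest adjusted p of these 0.045), but had an adjusted p = 0.56 with an estimated correlation. The 3 falls, named after their values were seen, were Os03g0751100 (-1.05), Os03g0644400 (-0.25) and Os06g0125500 (-0.23). Os03g0644400 is an amino acid permease, while the others are oligopeptide transporters that a list keyword took in. Os03g0644400 and Os06g0125500 changed sign with spike-in scaling. They also lost the call with slide as a block (adjusted p = 0.053 and 0.054) and without single arrays (adjusted p up to 0.11 and 0.14). Beside allantoinase, a urea transporter (Os10g0580400) rose by 1.69 (SE 0.21), and beside the fall of AS1, an asparaginase (Os04g0650700) rose by 1.48 (SE 0.19). These were chosen after their values were seen, as were the DUF125 protein Os09g0396900, with a rise of 3.36 (SE 0.06) and the smallest p of all loci, and a ferric reductase-like protein, Os04g0578600, with -2.13 (SE 0.28). Cytokinin metabolism had 1 locus higher, 5 lower and 8 not past the threshold of 14, with a mean of -0.21 that changed sign to 0.15 with spike-in scaling, and a camera adjusted p of 0.19. Its riser was CKX9 (Os05g0374200, 0.76), which breaks down cytokinin. Its falls were CKX3 (Os10g0483500, -0.42), CKX4 (Os01g0940000, -0.45), Os03g0848100 (-0.44), the isopentenyl transferase Os06g0729800 (-0.34, reversed with spike-in scaling) and Os05g0551700 (-1.89), all named after their values were seen. Each of these 6 calls ended in at least 4 alternatives, with slide as a block and the slide alone counted separately although they are nearly the same fit.

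In the main scaling camera called none of the lists that follow. Auxin had 17 of 90 loci higher and 6 lower (mean 0.07), cell wall 14 and 7 of 64 (0.09), starch and sucrose 9 and 10 of 51 (-0.03), redox enzymes 10 and 16 of 158 (-0.04), and phenylpropanoids 7 and 3 of 64 (0.09). Camera called auxin with normexp and 75th percentile scaling (adjusted p = 0.047) and without nitrogen-deficient replicate 3 (mean 0.09, adjusted p = 0.035), and fry called the cell wall list (adjusted p = 0.031). Camera with an estimated correlation gave an adjusted p of 0.68 for auxin and 0.56 for the cell wall list. With spike-in scaling the means of starch and sucrose (0.33), redox enzymes (0.32), heat shock (0.32), hemoglobin (0.34) and abscisic acid and dehydration (0.14) changed sign. Heat shock had 9 and 8 of 111 (mean -0.04, while fry pointed up), and its mean became 0.02 without control replicate 1 and -0.10 without control replicate 2. Jasmonate and wounding had 6 and 2 of 41, with a mean of 0.02 that was 0.12 with slide as a block, 0.09 without control replicate 3, -0.03 without control replicate 2, and also negative without nitrogen-deficient replicate 2. The mean of starch and sucrose was 0.0014 with slide as a block, and that of redox enzymes was -0.0088 without nitrogen-deficient replicate 3. The circadian clock had 1 of 8 loci higher (LHY, Os08g0157600, 0.30, adjusted p = 0.060 with slide as a block). Hemoglobin had 1 of 3 higher (Os06g0591600, 0.34, adjusted p = 0.063 with slide as a block), with a mean of -0.02, a median of 0.05 and a test pointing up. Its mean was 0.05 with slide as a block, and ran from -0.17 without control replicate 2 to 0.11 without control replicate 1. Abscisic acid and dehydration had 5 of 34 higher and 2 lower, with list means of 0.73 and -0.80 on control replicates 1 and 2. Its mean of -0.22 became 0.15 without control replicate 1 and -0.62 without control replicate 2. Root markers had 1 of 7 higher (NRAMP5, Os07g0257200, 0.40, adjusted p = 0.071 with slide as a block), with a mean of 0.09 that was -0.02 with slide as a block. That mean ran from -0.03 without control replicate 3 up to 0.23 when 1 other array was left out. Seed storage had 0 of 8 past the threshold in limma, with a mean of 0.17, a median of -0.02 and a test pointing down. When 1 array was left out, its mean ran from 0.12 to 0.27, and that of phenylpropanoids from 0.06 to 0.13.

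The lower signal of cytosolic ribosomal protein genes was weighed against a bias of bright probes and against slide or scan day. The list lay at -0.445 (SE 0.114) relative to loci of like signal, which themselves lay at -0.06, outside the 0.1 around 0 that a signal bias needs. The bound written beforehand, below -0.25 by more than 2 SE, was missed. Within the slide of both groups the list mean was -0.517, which a slide effect does not give. A candidate explanation left open is the nitrogen treatment itself, and the spike-in difference of 0.36 stays open for the absolute level.

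The many called probes were weighed against slide or scan day and against the grouping of the arrays. Of 4614 probes called within the slide of both groups, 90.6% had the same sign in nitrogen-deficient replicate 1 minus control replicate 3, arrays of other slides, against 71.1% of all tested probes. A slide effect was predicted to give about 50%. The bound written beforehand was over 90%, which the value only just passed, and 60% was used after the value was seen. The probes share 1 pair of arrays and are not independent, so no standard error is given for this share. The 6 arrays make only 10 splits, so the share, here 1 of 10, is never under 0.1; limma gave 7714 calls for the real split and at most 0 for the others.

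In the iron list, which camera did not call, the fall of 7 members beside the rise of 3 was weighed against 2 causes. These were root tissue in the control shoots and slide or scan day. The members that rose were the ferritins and the yellow stripe-like transporter Os04g0390500, so transporters went both ways. Root tissue would lower the root markers alike, but their mean was 0.0889 (SE 0.128, over the 7 measured markers and not over arrays). On the control arrays the mean of these markers ran from -0.314 to 0.213. The gap between the 3 higher and 7 lower members was 2.61 within the slide of both groups and 2.68 between the arrays of the other slides. These genes were picked because they had moved, so the gap does not test whether the pattern holds. An effect of the nitrogen treatment on iron status may underlie it, which these data do not test.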
